A study of Homo sapiens with 8 samples.

How the data were processed

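RNA was sequenced from K562, an established human cell line derived from a chronic myeloid leukaemia. The series holds 8 libraries, 4 from cells without Lip-1 (controls 1 to 4, labelled Day 0), 3 from cells given 10 µM Lip-1 (replicates 2 to 4) and 1 from cells given 20 µM Lip-1 (replicate 1). The treated libraries are labelled 24 h and Day 1. Doses and days are as labelled. The labels give 20 µM for replicate 1 alone, and no test here measures a dose, so what is said of 20 µM holds only as far as that label does. They do not say whether the controls received a vehicle. Lip-1 is not spelled out in the labels. The name is in common use for liproxstatin-1, an inhibitor of lipid peroxidation and of ferroptosis. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed with biotinylated probes, and the fragmented RNA was copied with random primers.

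The deposited table holds whole-number counts per gene and library, per the file header and the values. Per the submitters' processing notes, bcl2fastq 2.0, HISAT2, StringTie, DESeq2 and limma were used on the hg38 build, with no role, order or other version given in the sources used here. The table lists 19447 gene symbols, of which 19029 matched GENCODE release 29 and 18899 (97.18%) are protein-coding there. A further 9 lines without a gene name were left out of library sizes and tests. Low values were not spaced as single reads would be, with 2958 entries at 4 counts and 401 at 1 count, so a count may not be a single sequenced read, and floors and tests that rest on counts carry that limit. Total counts ran from 71151415 to 141307169 per library, and scaling factors by TMM (trimmed mean of M values) from 0.9029 to 1.085. Intervals and floors cover counting error only, with a floor of 3 counts for a library at 0.

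Levels in CPM were computed here as 1000000 times the count over the library's total, without the TMM factor. Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and, as an alternative, DESeq2 1.42.0. Genes were filtered with edgeR's filterByExpr, scaled by TMM and tested with the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was its size over the square root of the F statistic. The main comparison set the 4 treated against the 4 control libraries with no block. A fit with 3 levels gave 10 µM against control and the single 20 µM library against 10 µM, where the single library is assumed to vary like the others. A further fit tested whether the response differed between letters and digits in the submitters' library names (letters for controls 1 and 4, 20 µM replicate 1 and 10 µM replicate 4, digits for controls 2 and 3 and 10 µM replicates 2 and 3). That is a naming pattern, which the labels do not call a batch.

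In all, 34 gene lists were fixed before the data were examined, along with the comparisons, the alternatives to be tried and the rule for named genes. The lists cover DNA replication, G2 and mitosis, replication-dependent histones, cyclins and cyclin-dependent kinase (CDK) inhibitors of G1, pro-apoptotic genes, anti-apoptotic genes, caspases, pyroptosis, ferroptosis regulators, NRF2 targets, iron handling, cholesterol biosynthesis, fatty acid synthesis, lysosome, the ATF4 response, endoplasmic reticulum chaperones, heat shock proteins, immediate early genes, NF-kB and inflammatory genes, interferon-stimulated genes, STAT5 targets, ribosomal proteins, ribosome biogenesis, glycolysis and hypoxia, erythroid genes, heme biosynthesis, and markers of megakaryocytes, monocytes and granulocytes, lymphocytes, and epithelium and fibroblasts. The other 3 lists (mitochondrially encoded proteins, small structural RNAs and nuclear retained RNAs) had 0 members in the table used here and gave no result. Lists with 5 or more measured members (31 in the main comparison) were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. A count "adjusted over the list alone" uses Benjamini-Hochberg adjustment within that list.

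The named genes were chosen by rule. Part 1 takes, among genes past the threshold with a mean log2 CPM of 1 or more and every treated library above or below every control, the 10 with the largest positive and the 10 with the largest negative fold change. Part 2 takes 18 genes fixed in advance, and part 3 the 3 members of each list with the smallest p. Some of these genes and 1 list are not reported here. The list tests at each dose, the list counts without the 20 µM library and part 1 of the rule in the contrasts of 10 µM with control and 20 µM with 10 µM (for the latter without the separation of libraries) were added after the data were seen.

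The labels give controls and treated libraries the same replicate numbers. Deviations of log2 CPM from the group means correlated, across genes, between same-numbered control and treated libraries at 0.2506 to 0.4532, so the numbers were taken to pair the samples, and fits with the replicate number as a block are given where they change a call or move a count by more than 1.5 times. The labels do not say what a number shares, so the pairing rests on these correlations. In the submitters' library names, controls 1, 2 and 3 share their first character with the same-numbered treated library. Control 4 (A-C-1) shares it with control 1 (A-C) and not with 10 µM replicate 4 (B-E). The names thus do not bear out the pair of number 4. Whether controls 1 and 4 share a source is not stated. The correlations also follow the naming pattern. Control and treated libraries of 1 pattern correlated at 0.05044 or more and those of different patterns at -0.1352 or less. All 4 treated libraries correlated best with the control of their number, but only 3 controls with the treated library of theirs. Control 2 correlated at 0.3097 with 10 µM replicate 3 and at 0.2506 with replicate 2. Among the digit-named libraries, number and naming pattern are thus hardly told apart. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. No replicate pair within a group agreed within sampling noise (chi-square per gene 58.84 to 267.6). That measure takes each count as a single read, which may not hold here, so it cannot tell technical repeats from separate cultures.

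Alternatives were relative log expression and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2, limma-voom, the replicate block, the naming pattern as a covariate, removal of the histone list before scaling, fits within each naming pattern, and leaving out each library in turn. The procedure was tested on simulated counts with 200 genes changed, drawn from those with a mean of 20 or more counts. Libraries were drawn without numbered pairs or naming patterns. Far fewer genes were changed than were called in the data, so the shares below hold for that setting. For the main comparison (12910 genes) it recovered 6% of genes changed 1.5-fold, 34% at 2-fold, 76% at 4-fold and 86% at 8-fold, with 3.81% of calls false. For 10 µM against control (14380 genes) recovery was 16%, 68%, 78% and 84%, with 6.818% false. For 20 µM against 10 µM (14385 genes) it was 2%, 20%, 64% and 68%, with 2.532% false, and for the difference between naming patterns (13693 genes) 0%, 0%, 34% and 76%, with 6.78% false. In a simulated list test, with each gene drawn independently, the raised list was called and 0 of the 30 other lists were. With no correlation between genes, it does not measure false list calls in these data. Other splits of the 8 libraries gave up to 17 called lists. Gene coordinates are those of GENCODE release 29 on GRCh38 (hg38).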

Results

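The series asked how Lip-1 changes gene expression in K562 cells, and its title names cell cycle arrest, apoptosis and pyroptosis. K562 is a human erythroleukaemia line that carries BCR-ABL1 and expresses embryonic and fetal globins. Counts were analysed for 8 libraries, 4 controls without Lip-1 (Day 0), 3 at 10 µM and 1 at 20 µM for 24 h (Day 1). Total counts were 141307169, 81230924, 79063246 and 91814646 in controls 1 to 4. They were 124240276 in the 20 µM library (replicate 1) and 72316071, 71151415 and 72660803 in 10 µM replicates 2 to 4. Treatment and day label coincide in every library, so each contrast with control is also Day 1 against Day 0. The 20 µM dose has a single library, and its values have no replicate check.

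**Figure D1:**
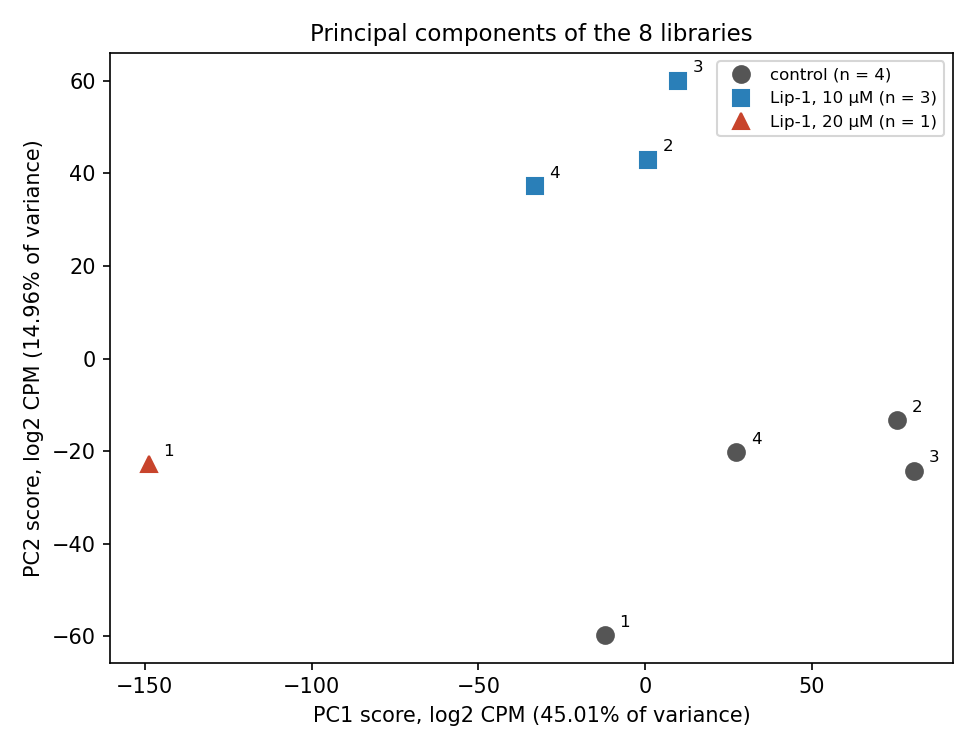
Scores of the 8 libraries on the first principal components of log2 CPM, with PC1 (45.0% of the variance) on the x axis and PC2 (14.96%) on the y axis, numbered by replicate. The 20 µM library lies at -148.8 on PC1, the 10 µM libraries between -33.1 and 9.83, and the controls between -12.1 and 80.6.

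The main comparison set the 4 treated libraries against the 4 controls. CXCL8, a chemokine (chromosome 4, 73740506 to 73743716), had the largest rise of the genes named by rule, from 1.58 ± 0.733 CPM in the controls (SD, n = 4) to 140 ± 77.45 at 10 µM (n = 3) and 1222 at 20 µM, a log2 fold change of 7.91 (SE 1.11, edgeR adjusted p = 0.00936). KCP, PHLDA1, RELB (an NF-kB subunit), ATF3 (a stress-induced transcription factor), FBXO32, LURAP1L, DUSP8 and SLCO2B1 (an organic anion transporter) rose by 4.51 to 6.07 on the log2 scale. Without the 20 µM library these 8 stood at 2.45 to 3.82, and DUSP8 lost its call (adjusted p = 0.0542). Of the 92 named genes past the threshold, 16 moved by more than 1.5 times without it, all 16 to a smaller fold change, among them CDKN1A (2.40), SLC7A11 (1.70), BIRC3 (2.67), AIM2 (3.49), SQSTM1 (1.83), OSGIN1 (1.57), HERPUD1 (1.13), ITGB3 (2.90) and RASGRP3 (1.79). ATF3 stood at 5.89 ± 3.28 CPM in the controls (n = 4), 40.3 ± 22.0 at 10 µM (n = 3) and 607.8 at 20 µM. NEFH, a neurofilament gene (chromosome 22, 29480230 to 29491390), had the largest fall, from 109.4 ± 20.1 CPM (n = 4) to 24.1 ± 4.94 (n = 3) and 9.29, a log2 fold change of -2.55 (SE 0.34, edgeR adjusted p = 0.00918). CITED1, HBZ (embryonic zeta globin), WNT10B, TMEM52, KCNH4, CD3EAP, HBA1, HBA2 and PGAM4 fell, with log2 fold changes of -2.30 to -1.51. HBA1 and HBA2 are near-identical copies and PGAM4 resembles PGAM1, so how their counts were split is uncertain. As the rule for part 1 requires, these genes were above, or below, every control in 4 of 4 treated libraries. With the 20 µM library in the group, the treated libraries spread widely (CXCL8, 410.6 ± 544.8 CPM, SD, n = 4).

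By edgeR, 1855 of 13101 genes passed the threshold, 979 higher and 876 lower, and 2815 did with the replicate number as a block, 1726 of them among the 1855. Treated and control libraries did not overlap in 3673 genes (28.0%), where chance gives 2.86%. The median log2 fold change of all genes was 0.08 under TMM, 0.07 under relative log expression and 0.14 under upper-quartile scaling. The balance of calls moved with the scaling, at 933 higher and 938 lower under relative log expression and 1147 and 728 under upper-quartile. The count rests on single libraries. It was 567, 149, 64 and 315 without controls 1, 2, 3 and 4, 814 and 312 without 10 µM replicates 3 and 4, and 3021 without the 20 µM library (1808 shared with the 1855). Of the 92 named genes past the threshold, 51, 71, 78 and 68 lost their call without controls 1, 2, 3 and 4, and 30 and 59 without 10 µM replicates 3 and 4, while 0 changed direction. Genes with all treated libraries on the same side of every control, as the rule for part 1 requires, could hardly change direction this way.

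**Figure D2:**
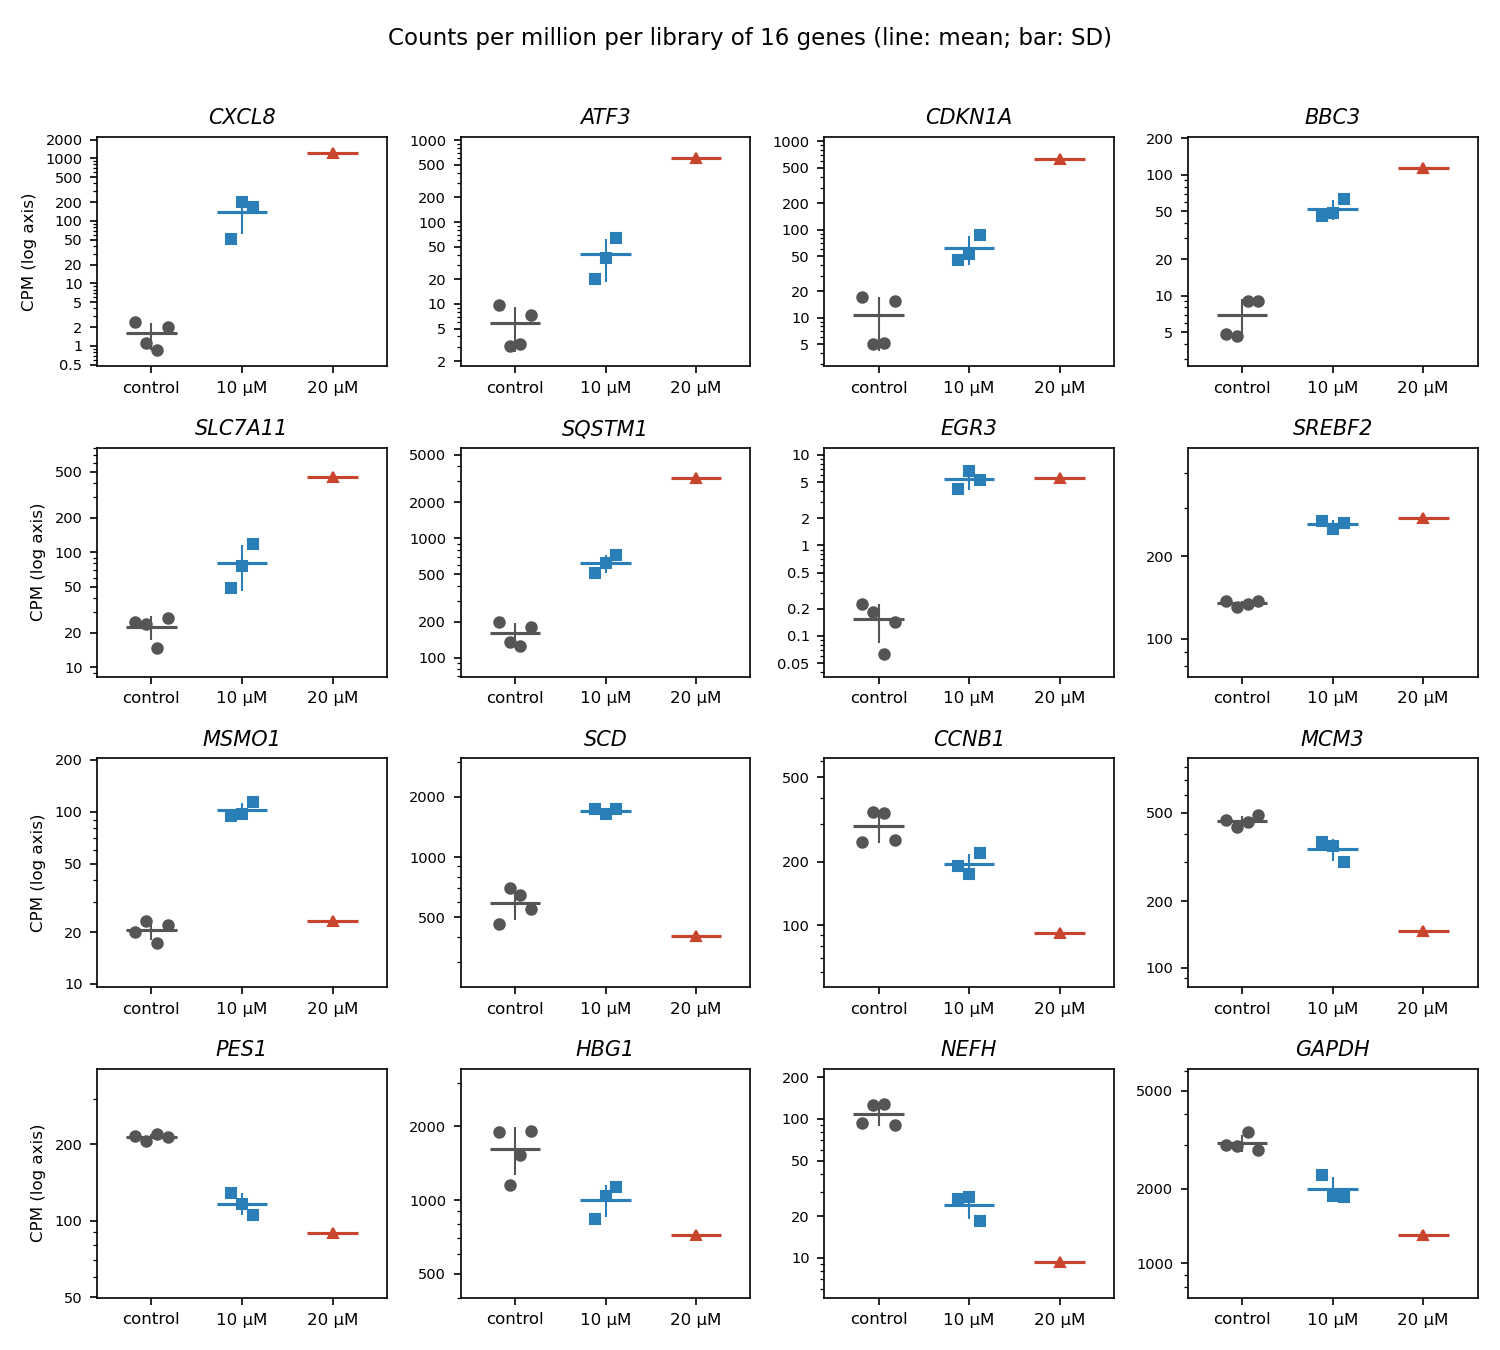
CPM (log axis) of 16 named genes in each control (n = 4), 10 µM (n = 3) and 20 µM (n = 1) library, with the mean as a line and the SD as a bar. MSMO1 and SCD, of sterol and fatty acid synthesis, are higher at 10 µM than in every control and stand at 23.1 and 402.7 CPM at 20 µM, where CXCL8, ATF3 and CDKN1A stand at 1222, 607.8 and 624.3.

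Across the fixed gene lists, camera called 18 of 31, 10 higher and 8 lower, and 0 with an estimated correlation. Fry, which tests whether a list's genes move on balance in 1 direction, called 12, of which 10 are among the 18. Its test for change in either direction called 19.

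Of the cell cycle genes, CDKN1A (p21, a CDK inhibitor, chromosome 6, 36676460 to 36687339) rose from 10.8 ± 6.55 CPM (SD, n = 4) to 62.2 ± 22.5 at 10 µM (n = 3) and 624.3 at 20 µM, a log2 fold change of 4.14 (SE 0.97, edgeR adjusted p = 0.0309). CCNB1 (cyclin B1) fell by 0.94 (SE 0.26, adjusted p = 0.0466), while CDK1 (-0.35, adjusted p = 0.372) and CCND1 (0.10, adjusted p = 0.708) did not pass. Of 19 measured G1 regulators 5 rose and 0 fell (8 and 1 adjusted over the list alone), among them RBL2 (0.64), CDKN1B (0.61) and BTG2 (2.14), and camera did not call the list (adjusted p = 0.105). Of 40 DNA replication genes 1 was called, POLD1, which fell by 0.66 (0 adjusted over the list alone, 2 lower with the replicate block, 11 without the 20 µM library). MCM5 (-0.53, adjusted p = 0.061) and MCM3 (-0.77, adjusted p = 0.0746, 0.0457 with the block), subunits of the replicative helicase, had the next smallest p. Of 34 G2 and mitosis genes 3 fell, CDC20 (-1.02), PLK1 (-0.997) and CCNB1, and 0 rose (2 lower adjusted over the list alone, 12 with the block, 1 higher and 8 lower without the 20 µM library). The medians of these lists were -0.49 and -0.39, and -0.27 and -0.21 at 10 µM against control (camera adjusted p = 3.87e-07 and 6.17e-05, and adjusted p = 0.494 and 0.502 with an estimated correlation). Of 32 replication-dependent histone genes 7 rose, among them H2BC5 (1.01), H4C8 (1.57) and H4C5 (1.69), and 0 fell (10 adjusted over the list alone, 11 with the block). Their median was 0.84. The camera test gave adjusted p = 6.17e-05, and adjusted p = 0.494 with an estimated correlation. Histone copies share sequence, so their counts are uncertain.

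Of the apoptosis genes, BBC3 (PUMA, a BH3-only activator) went from 6.89 ± 2.44 CPM (SD, n = 4) to 52.3 ± 9.88 at 10 µM (n = 3) and 114.2 at 20 µM, a log2 fold change of 3.17 (SE 0.39, edgeR adjusted p = 0.00747). BMF (2.66) and BOK (0.99) rose too, in a list of 17 pro-apoptotic genes with 5 higher and 0 lower (6 and 1 adjusted over the list alone, 5 and 1 with the block, 6 and 2 without the 20 µM library, camera adjusted p = 0.0904). Of 9 anti-apoptotic genes 4 rose and 0 fell (6 and 1 adjusted over the list alone, 6 and 1 with the block), among them BIRC3 (4.01), XIAP (1.18) and CFLAR (0.47), inhibitors of caspase activation. For this list camera gave adjusted p = 0.02875, and adjusted p = 0.356 with an estimated correlation. BCL2 (0.72, adjusted p = 0.09805) and MCL1 (1.22, adjusted p = 0.0627) did not pass, but did with the block (adjusted p = 0.0382 and 0.0400). Of 14 caspase and apoptosome genes 4 rose, among them APAF1 (0.83) and CASP8 (0.95), and 1 fell, HTRA2 (-0.56) (5 and 3 adjusted over the list alone, 6 and 3 with the block, 4 and 4 without the 20 µM library, camera adjusted p = 0.703).

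Of 13 measured pyroptosis and inflammasome genes 2 rose, NEK7 (0.71) and AIM2 (5.91), and 1 fell, HMGB1 (-1.18), a chromatin protein released from dying cells (2 and 1 adjusted over the list alone, 5 and 1 with the block). The list median was 1.06, and 0.69 at 10 µM against control. Against the control mean, the 20 µM library stood at 2.19 and 10 µM replicates 2, 3 and 4 at 0.40, 0.47 and 1.35. Control 1 stood at 0.51, above 10 µM replicates 2 and 3. By camera the list had adjusted p = 0.0289, and adjusted p = 0.494 with an estimated correlation. It lost its call without the 20 µM library (0.1196), without control 2 (0.07305), with the filter of 1 CPM (0.201) and with upper-quartile scaling (0.0516). AIM2, a DNA sensor, was near the floor in the controls, at 0.0890 ± 0.117 CPM (SD, n = 4), and stood at 1.17 ± 0.754 at 10 µM (n = 3) and 21.0 at 20 µM. The pore-forming gasdermins did not pass in the main comparison. GSDME stood at 0.337 ± 0.137, 0.615 ± 0.776 and 13.9 CPM in those groups (edgeR adjusted p = 0.149) and GSDMD at 0.202 ± 0.305, 0.688 ± 0.222 and 1.94 CPM (adjusted p = 0.2565). Between the single 20 µM library and 10 µM, GSDME differed by 4.525 on the log2 scale (5.169 with the block). It passed there without the block and not with it.

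Of 20 measured ferroptosis regulators 3 rose and 2 fell (5 and 2 adjusted over the list alone, 5 and 2 with the block, 6 and 3 without the 20 µM library, camera adjusted p = 0.286). SLC7A11, the cystine transporter (chromosome 4, 138164097 to 138242349), rose from 22.55 ± 5.26 CPM (SD, n = 4) to 80.8 ± 34.6 at 10 µM (n = 3) and 452.7 at 20 µM, a log2 fold change of 2.84 (SE 0.66, edgeR adjusted p = 0.0302). VDAC2 (-0.45) and DHODH (-1.24), a mitochondrial enzyme of pyrimidine synthesis, fell. GPX4, the lipid peroxide reductase, stood at 0.12 (SE 0.18, adjusted p = 0.677), TFRC at 0.30 (adjusted p = 0.470) and FTH1, ferritin heavy chain, at 0.53 (adjusted p = 0.396). Without the 20 µM library GPX4 stood at -0.08 and FTH1 at -0.10. HMOX1 was too low to be tested in the main comparison, at 0.0319 ± 0.0637 CPM in the controls (n = 4), 0.106 ± 0.160 at 10 µM (n = 3) and 0.137 at 20 µM. In the fit with 3 levels it did not pass (adjusted p = 0.649 at 10 µM against control and 0.945 at 20 µM against 10 µM). Of 24 NRF2 targets and glutathione genes 4 rose and 1 fell (5 and 2 adjusted over the list alone, 2 and 2 with the block, 7 and 3 without the 20 µM library, camera adjusted p = 0.0700), led by SQSTM1 (2.88, from 159.8 ± 36.0 CPM, n = 4) and SLC7A11, while OSGIN1 (3.995, adjusted p = 0.0432) lost its call with the block (adjusted p = 0.0734). Of 15 iron genes 0 rose and 1 fell, STEAP3 (-1.09), an endosomal ferrireductase (0 adjusted over the list alone, 2 lower with the block, 2 higher and 3 lower without the 20 µM library, camera adjusted p = 0.0940). TFR2 stood at -0.94 (adjusted p = 0.0652).

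Of 25 cholesterol synthesis genes 8 rose and 0 fell (16 adjusted over the list alone, 22 higher without the 20 µM library). SREBF2, the transcription factor of the pathway, rose from 134.5 ± 2.83 CPM (SD, n = 4) to 261 ± 9.75 at 10 µM (n = 3) and 275.4 at 20 µM, a log2 fold change of 0.86 (SE 0.10, edgeR adjusted p = 0.00747). It lay above every control in 4 of 4 treated libraries, and MSMO1 (1.875) in 3 of 4. The list median was 1.03. The list had, by camera, adjusted p = 0.000179, and adjusted p = 0.494 with an estimated correlation. Of 14 fatty acid synthesis genes 2 rose, LPIN1 (1.38) and ACSS2 (1.53), and 0 fell (2 adjusted over the list alone, 6 higher without the 20 µM library, camera adjusted p = 0.101), with SCD, the stearoyl-CoA desaturase, at 1.09 (adjusted p = 0.0966). Of 26 lysosome genes 10 rose and 1 fell (16 and 1 adjusted over the list alone, 14 and 0 with the block). The cholesterol exporters NPC2 (1.93) and NPC1 (0.97) rose. The camera test of the lysosome list gave adjusted p = 0.000146, and adjusted p = 0.494 with an estimated correlation.

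Of 27 ATF4 response genes 7 rose and 0 fell (18 adjusted over the list alone, 14 with the block, 15 without the 20 µM library), with a median of 1.64, and 0.71 at 10 µM against control. The 20 µM library stood 2.77 above the control mean at the list median, and the 10 µM libraries 0.38 to 1.20. Camera gave adjusted p = 1.99e-05, and adjusted p = 0.494 with an estimated correlation. GDF15, a stress cytokine, went from 29.7 ± 13.8 CPM (SD, n = 4) to 178.8 ± 23.65 at 10 µM (n = 3) and 881.2 at 20 µM, and ASNS, asparagine synthetase, rose by 1.51. Of 20 endoplasmic reticulum chaperone genes 1 rose, HERPUD1 (2.39), and 0 fell (0 adjusted over the list alone, 3 and 3 without the 20 µM library, camera adjusted p = 0.513), with EDEM1 at 1.54 (adjusted p = 0.0615) and DNAJB9 at 2.13 (adjusted p = 0.0650). Of 17 heat shock genes 5 fell, among them HSP90AB1 (-0.77) and DNAJA1 (-0.72), and 1 rose, DNAJB4 (1.08) (7 lower and 1 higher adjusted over the list alone, 8 and 1 with the block, camera adjusted p = 0.000941, and adjusted p = 0.356 with an estimated correlation).

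Of 15 measured NF-kB and inflammatory genes 10 rose and 0 fell (12 adjusted over the list alone), with a median of 2.96, and 1.96 at 10 µM against control. For this list camera gave adjusted p = 7.21e-06, and adjusted p = 0.492 with an estimated correlation. Besides CXCL8 these included IL6 (2.89) and IL1A (7.15), which was at 0 in controls 2 to 4. Of 24 immediate early genes 10 rose and 0 fell (12 adjusted over the list alone), with a median of 1.23, and 0.58 at 10 µM against control. By camera the list had adjusted p = 1.35e-05, and adjusted p = 0.441 with an estimated correlation. EGR3 rose from 0.154 ± 0.0697 CPM (SD, n = 4) to 5.41 ± 1.27 at 10 µM (n = 3) and 5.53 at 20 µM, a log2 fold change of 5.01 (SE 0.42, edgeR adjusted p = 0.00349), and NR4A1 (3.07) and EGR2 (2.73) rose too. Of 18 interferon-stimulated genes 6 rose and 0 fell (8 adjusted over the list alone, 10 with the block), among them IFIT1 (5.15), IFIT3 (4.20) and OASL (7.58, near the floor in the controls), with a median of 1.84, and 0.62 at 10 µM against control. Against the control mean, the 20 µM library stood at 3.22 and 10 µM replicates 2, 3 and 4 at 0.66, 0.43 and 1.45, with control 1 at 0.63. The list had, by camera, adjusted p = 0.00117, and adjusted p = 0.494 with an estimated correlation. Of 10 STAT5 targets, which BCR-ABL1 signalling drives, edgeR called 0 (0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom), and camera did not call the list (adjusted p = 0.736). SOCS2 stood at 0.29 (adjusted p = 0.2735), SOCS3 at 0.57 (adjusted p = 0.402) and ID1 at -0.31 (adjusted p = 0.434). MYC stood at 0.22 (SE 0.38, adjusted p = 0.722), and at -0.47 in the digit-named libraries alone (adjusted p = 0.02025).

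Of 28 genes of ribosome biogenesis 22 fell and 0 rose (24 adjusted over the list alone), with a median of -0.97. Its camera test gave adjusted p = 4.13e-14, and adjusted p = 0.360 with an estimated correlation. PES1, of the large-subunit assembly complex, went from 213.5 ± 5.82 CPM (SD, n = 4) to 116.5 ± 11.4 at 10 µM (n = 3) and 89.6 at 20 µM, and RRP9 (-1.45) and NOP2 (-1.01) fell too. Of 38 ribosomal protein genes 2 fell, RPL38 (-0.45) and RPL8 (-0.39), and 0 rose (0 adjusted over the list alone, 5 lower with the block, 5 without the 20 µM library), with RPS15 at -0.45 (adjusted p = 0.0547) and a list median of -0.21. Camera gave adjusted p = 5.52e-05, and adjusted p = 0.494 with an estimated correlation. Of 26 glycolysis and hypoxia genes 7 fell and 2 rose (8 and 3 adjusted over the list alone, 12 lower and 4 higher without the 20 µM library), among them PFKFB3 (-0.66), GPI (-0.93) and GAPDH (-0.87). The median of that list was -0.35 and its mean 0.002111, which differ in sign (camera, lower, adjusted p = 0.02695, and adjusted p = 0.356 with an estimated correlation).

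Of 24 globin and erythroid genes 7 fell and 0 rose (8 adjusted over the list alone, 12 with the block, 11 without the 20 µM library), with a median of -0.76. The camera test gave adjusted p = 1.15e-05, and adjusted p = 0.3975 with an estimated correlation. The fetal globin HBG1 went from 1621 ± 361.2 CPM (SD, n = 4) to 1003 ± 151 at 10 µM (n = 3) and 717.9 at 20 µM, a log2 fold change of -0.92 (SE 0.19, edgeR adjusted p = 0.0236). Its near-identical copy HBG2 (-0.835) lay below every control in 3 of 4 treated libraries, and HBQ1 (-1.15) and HBA1 (-1.635) fell too. Of 13 heme synthesis genes 1 fell and 0 rose (1 adjusted over the list alone, 2 with the block, 1 higher and 2 lower without the 20 µM library), with FECH at -0.51 (adjusted p = 0.0657, 0.0391 with the block) and ABCB10 at -0.38 (adjusted p = 0.0823). For this list camera gave adjusted p = 0.02875, and adjusted p = 0.494 with an estimated correlation. The call was lost without the 20 µM library (0.1196) and with the filter of 1 CPM (0.0534). Of 13 megakaryocyte markers 2 rose, the tetraspanin CD9 (2.87) and the integrin ITGB3 (4.47), and 0 fell (2 adjusted over the list alone, camera adjusted p = 0.343), with GP6 at 1.44 (adjusted p = 0.155, 0.0275 with the block).

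Markers of other cell types were tested as well. Of 7 monocyte and granulocyte markers (ITGAX, CD14 and CD68 with the smallest p) and 7 lymphocyte markers (NKG7, CD3E and CD79A), edgeR called 0, as did DESeq2 and limma-voom (0 adjusted over each list alone, 1 and 0 at an unadjusted p under 0.05, 1 and 0 with the block). Camera called neither list (adjusted p = 0.593 and 0.729). ITGAX had adjusted p = 0.113 without and 0.0244 with the block. Of 8 epithelial and fibroblast markers 1 rose, the keratin KRT19 (0.90), from 64.75 ± 21.5 CPM in the controls (SD, n = 4), and 0 fell (1 adjusted over the list alone, 2 higher with the block, camera adjusted p = 0.343). KRT8 stood at 0.59 (adjusted p = 0.116, 0.0234 with the block) and DCN at 1.04 (adjusted p = 0.2004).

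**Figure D3:**
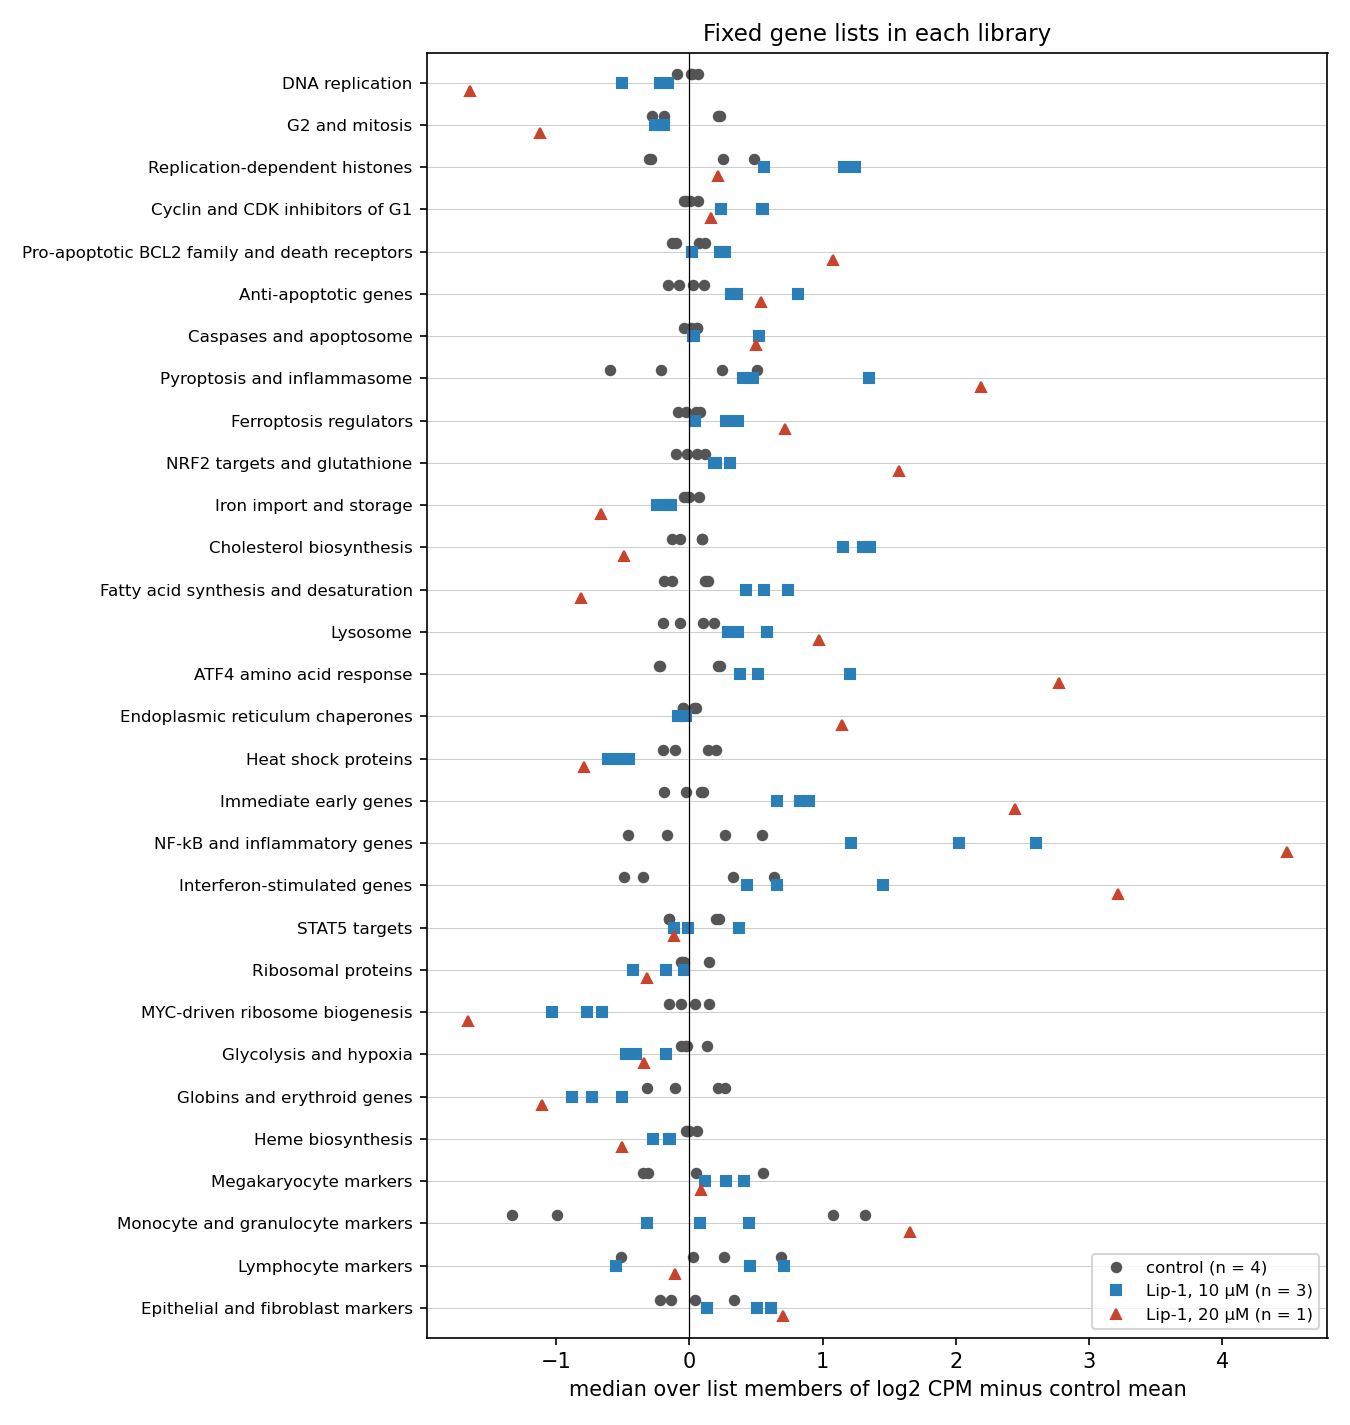
Median over the measured members of each of 30 lists of log2 CPM minus the control mean (x axis), for each control (n = 4), 10 µM (n = 3) and 20 µM (n = 1) library. Cholesterol genes lie above the controls in the 10 µM libraries and below them at 20 µM, and ribosome biogenesis genes lie below the controls in all 4 treated libraries.

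The contrast of 10 µM with control asks what the lower dose alone did. Of 25 cholesterol synthesis genes 22 rose and 0 fell (24 adjusted over the list alone), with a median log2 fold change of 1.30. By camera the list had adjusted p = 2.4e-15, and adjusted p = 0.260 with an estimated correlation. MSMO1, a sterol oxidase, went from 20.6 ± 2.61 CPM (SD, n = 4) to 101.8 ± 10.7 (n = 3), a log2 fold change of 2.18 (SE 0.12, edgeR adjusted p = 0.000138), and all 3 libraries lay above every control. Of 15 fatty acid genes 6 rose, among them SCD (1.39), LPIN1 (1.55) and ACSS2 (1.79), and 0 fell (6 adjusted over the list alone, 10 with the block, camera adjusted p = 2.99e-05, and adjusted p = 0.260 with an estimated correlation). Ribosome biogenesis genes fell in 24 of 28 cases and rose in 0 (26 lower adjusted over the list alone, camera adjusted p = 6.37e-16, and adjusted p = 0.260 with an estimated correlation). CDKN1A (2.41), BBC3 (2.79), SLC7A11 (1.71), GDF15 (2.48) and TFRC, the transferrin receptor (0.52), rose, and CCNB1 (-0.74), HBG1 (-0.82) and GAPDH (-0.75) fell. MYC (-0.40, edgeR adjusted p = 0.0665) did not pass. It passed with the block (adjusted p = 0.00455) and in the digit-named libraries alone (-0.47, adjusted p = 0.02025). GSDMD (1.65, adjusted p = 0.441) passed with the block (adjusted p = 0.0144). By the rule for named genes applied here, CXCL8 (6.33), SLCO2B1 (3.82), PHLDA1 (3.73), SIGLEC6 (3.57), MCOLN3 (3.19), FBXO32, ITGB3, SLCO4C1 (2.87) and IFIT3 rose most, and NEFH (-2.31), HBZ, SMN2 (-2.03, with a near-identical copy), CITED1, WNT10B, HBA1, HBA2, ZNF296 (-1.55), TNFRSF8 (-1.51) and KCNH4 fell most.

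Other lists at 10 µM are given as genes higher and lower of those measured. Camera called NF-kB genes (13 and 0 of 20, adjusted p = 3.21e-06), immediate early genes (11 and 0 of 24, 0.000113), ATF4 genes (14 and 0 of 28, 5.06e-05), lysosome genes (13 and 1 of 26, 0.000304), histones (9 and 0 of 33, 2.52e-06) and interferon genes (7 and 0 of 21, 0.00791) towards higher levels. It called DNA replication (0 and 11 of 40, 2.87e-07), G2 and mitosis (1 and 6 of 34, 0.00295), heat shock (1 and 5 of 17, 0.000122), ribosomal protein (0 and 4 of 38, 9.72e-05), glycolysis (4 and 12 of 26, 0.0133) and erythroid genes (0 and 10 of 25, 1.74e-05) towards lower levels. Adjusted over the list alone, the counts were 13 and 0, 12 and 1, 17 and 0, 15 and 1, 15 and 0, and 8 and 1 for the lists called higher, in that order. For the lists called lower they were 0 and 13, 1 and 6, 1 and 10, 0 and 0, 6 and 14, and 0 and 11. With the replicate block 16 histone and 12 interferon genes were higher, 20 ATF4 genes were higher and 1 lower, and 14 immediate early genes were higher and 1 lower. In that fit 18 DNA replication genes were lower, as were 16 of G2 and mitosis, 14 heat shock, 14 ribosomal protein and 16 erythroid genes. G1 regulators (7 and 0 of 19, 8 and 0 adjusted over the list alone, 9 and 1 with the block, camera adjusted p = 0.0311) lost their call with the replicate block (0.113), and pyroptosis genes (2 and 1 of 19, the same adjusted over the list alone, 7 and 1 with the block, 0.128) gained it (0.0309). Camera called neither pro-apoptotic (6 and 1 of 19, adjusted p = 0.369), anti-apoptotic (4 and 1 of 10, 0.0656) nor caspase genes (4 and 3 of 15, 0.743), and neither ferroptosis regulators (5 and 3 of 22, 0.369), NRF2 targets (7 and 3 of 26, 0.316) nor iron genes (2 and 3 of 16, 0.117). Endoplasmic reticulum chaperones (3 and 3 of 20, 0.666) and heme synthesis genes (1 and 2 of 13, 0.111) were not called either. Adjusted over the list alone these 8 had 6 and 3, 5 and 1, 4 and 4, 8 and 3, 7 and 3, 2 and 3, 3 and 3, and 1 and 2. With the block pro-apoptotic genes had 6 and 3, caspase genes 7 and 4 and ferroptosis regulators 10 and 5. Of 11 STAT5 targets 0 passed (0 adjusted over the list alone, 2 and 1 with the block, camera adjusted p = 0.634). Markers of megakaryocytes (2 and 0 of 14, camera adjusted p = 0.181), monocytes and granulocytes (0 and 0 of 11, 0.999), lymphocytes (0 and 0 of 10, 0.999) and epithelium and fibroblasts (1 and 0 of 15, 0.321) kept these counts when adjusted over the list alone, and had 5 and 0, 1 and 0, 0 and 0, and 2 and 1 with the block. With an estimated correlation none of the 17 called lists passed, with adjusted p from 0.260 to 0.603. By edgeR 2842 of 14857 genes passed, 1387 higher and 1455 lower, and 4657 with the replicate block, 2793 of them among the 2842. The count was 1364 and 1463 without 10 µM replicates 3 and 4, and 1880 and 1640 without controls 2 and 3. More genes were higher than lower with upper-quartile scaling (1546 and 1333) and with the replicate block (2406 and 2251).

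The contrast of 20 µM with 10 µM asks what a higher dose did at the same 24 h, from 1 library at 20 µM. That library's distance was set against the spread pooled over the other groups, so its calls describe this library, not the dose. With the replicate block it is paired with control 1 alone, so its values with the block rest on that single control. Cholesterol genes were lower there than at 10 µM in 21 of 25 cases and higher in 0 (median -1.79), and MSMO1 stood at 23.1 CPM, against 101.8 ± 10.7 at 10 µM (SD, n = 3) and 20.6 ± 2.61 in the controls (n = 4). Fatty acid genes were lower in 10 of 15 cases and higher in 1 (10 and 2 with the block, median -1.47), with SCD at 402.7 CPM, against 591.7 ± 106 in the controls (n = 4). The contrasts share the 10 µM libraries, so opposite signs arise in part by construction. Against the mean of all controls, the cholesterol list had a median of -0.49 in the 20 µM library. DNA replication genes were lower in 33 of 40 cases and higher in 0 (median -1.32), with MCM3 at 147.2 CPM, against 341.2 ± 37.2 at 10 µM (n = 3). G2 and mitosis genes were lower in 22 of 34 cases and higher in 1 (lower in 9 and higher in 0 with the block), and CDK1 stood at 78.8 CPM, against 183.3 ± 18.3 (n = 3).

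In the same library, ATF4 response genes were higher than at 10 µM in 21 of 28 cases and endoplasmic reticulum chaperones in 16 of 20, with 0 lower in both (medians 1.92 and 1.04). NRF2 and glutathione genes were higher in 18 of 26 cases and lower in 0, with SQSTM1 at 3202 CPM, against 621.8 ± 106 at 10 µM (SD, n = 3). FTH1 stood at 6227 CPM, against 2027 ± 669 (n = 3), and TFRC at 495, against 1196 ± 117.3. MYC stood at 707.7 CPM, against 230.1 ± 19.3 (n = 3), while ribosome biogenesis genes were lower in 19 of 28 cases and higher in 1. NF-kB genes were higher in 13 of 20 cases, immediate early genes in 12 of 24, pro-apoptotic genes in 4 of 19 (4 higher and 1 lower with the block), lysosome genes in 10 of 26 (5 higher and 2 lower with the block) and interferon genes in 9 of 21 (6 with the block), with 0, 0, 0, 1 and 1 lower. Of the genes the rule names, IER3, KCP, RSAD2, C3, HSPA1A, RELB, KLF4, OSGIN1, HSPA1B and RASGRP3 were higher by 4.04 to 5.41 on the log2 scale, and CT45A9 (-7.48), SLX1A, ARHGAP22, LIN28A, ANKRD55, CD36, TRDN, RHOXF2 and CYP26A1 (-4.20) were lower. SLX1A (edgeR adjusted p = 0.0406) and RHOXF2 (0.0381) lost their calls with the replicate block (0.0667 and 0.0596). With the block IER3 stood at 1.73 (5.41 without), KCP at 3.19 (5.18), HSPA1A at 1.29 (4.26), HSPA1B at 1.37 (4.06), CD36 at -2.65 (-4.75) and SLX1A at -0.88 (-6.475). GTF2H2C had 0 counts there, which allows up to 0.0242 CPM (3 counts in this library), at least 1327-fold lower than the 32.0 ± 4.63 CPM at 10 µM (n = 3). GTF2H2C, SLX1A, CT45A9, RHOXF2, HSPA1A and HSPA1B have near-identical copies, so their counts are uncertain.

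Of 14857 genes, 3903 lay outside the pooled spread between 20 µM and 10 µM by edgeR, 1734 higher and 2169 lower. Camera called 17 of 31 lists, 9 higher and 8 lower, and with an estimated correlation 0 (adjusted p 0.149 to 0.640 for those 17). Besides the lists above, it called pyroptosis (5 higher and 0 lower of 19, 3 and 0 with the block, adjusted p = 0.0151, 0.131 with the block), histones (0 and 5 of 33, adjusted p = 0.0151, 0.262 with the block), heme synthesis (0 and 7 of 13, adjusted p = 0.0188) and erythroid genes (0 and 7 of 25, 1 and 9 with the block, adjusted p = 0.0435). Adjusted over the list alone, 22 cholesterol, 11 fatty acid, 37 DNA replication, 27 G2 and mitosis, 19 ribosome biogenesis, 5 histone, 7 heme and 7 erythroid genes were lower. By the same measure 25 ATF4, 18 NRF2, 16 chaperone, 15 NF-kB, 12 immediate early, 8 pro-apoptotic, 10 lysosome, 10 interferon and 5 pyroptosis genes were higher. Megakaryocyte markers (2 and 4 of 14, adjusted p = 0.750) gained a call with the block (adjusted p = 0.0405). Camera did not call caspases (0 and 4 of 15, adjusted p = 0.485), anti-apoptotic genes (2 and 1 of 10, 0.410), ferroptosis regulators (9 and 5 of 22, 0.1205), iron genes (3 and 7 of 16, 0.366), glycolysis (6 and 10 of 26, 0.639), G1 regulators (3 and 4 of 19, 0.639) or heat shock genes (5 and 3 of 17, 0.571). Nor did it call STAT5 targets (2 and 3 of 11, 0.917), ribosomal proteins (0 and 1 of 38, 0.365), or markers of monocytes and granulocytes (1 and 0 of 11, 0.414), lymphocytes (0 and 1 of 10, 0.917) and epithelium and fibroblasts (0 and 0 of 15, 0.917). Adjusted over the list alone these 12 had 0 and 4, 2 and 2, 10 and 6, 4 and 8, 7 and 11, 4 and 4, 5 and 7, 2 and 4, 0 and 0, 0 and 0, 0 and 1, and 0 and 0. With the block anti-apoptotic genes had 2 and 2, heat shock genes 3 and 3, ribosomal proteins 0 and 0, monocyte and granulocyte markers 0 and 1, and epithelial and fibroblast markers 0 and 2. Of the STAT5 targets, SOCS3 was higher at 20 µM than at 10 µM (1.82, adjusted p = 0.00289) and ID1 lower (-1.21, adjusted p = 0.00324), also with the block.

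A last comparison asked whether the treated-control difference itself differed between the letter-named and digit-named libraries, each with 2 controls and 2 treated libraries. By edgeR 0 of 14014 genes passed (473 at an unadjusted p under 0.05), by limma-voom 0 (417 unadjusted) and by DESeq2 12 (744 unadjusted). Within the digit-named libraries, both treated ones at 10 µM, edgeR called 3137 genes, limma-voom 3294 and DESeq2 3810. Within the letter-named ones, with 1 treated library at 20 µM and 1 at 10 µM, edgeR called 0 (2694 unadjusted), limma-voom 0 and DESeq2 1462. The test of the difference called 2958 genes without 10 µM replicate 4, where the 20 µM library alone stands for the letter-named treated cells, and 9 without the 20 µM library.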

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

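Among the tests below, those for cells of another type, for the 10 µM response carried further, for a dose-dependent change and for culture day were chosen after their result was seen, and the thinning and the fits that leave out a library with a further term were added after seeing the data. The test of the response carried further was split into all genes and the cholesterol list once its values were known. As first written it asked for 90% or more in both and failed on a cholesterol share under 50%.

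The values of the 4 controls were tested for 153 items, namely log2 CPM of named genes, mean log2 CPM of lists, and total counts. In 6 of these, all named genes, 1 library lay apart by Dixon's ratio (over its critical value). That is no more than chance gives, at about 1 in 20. Among the 6 were SLC7A11 in control 3 (ratio 0.851, 4.04 against 4.65 to 4.75), HBG2 in control 2 (0.886, 11.08 against 11.72 to 11.8), SREBF2 in control 3 (0.841, 7.21 against 7.10 to 7.12) and PES1 in control 3 (0.906, 7.93 against 7.75 to 7.77). The others were HMOX1 (-2.74 against -5.52, which is 0 counts) and IL1A (-3.67 against -5.52), both in control 1. With the other controls all at 0 counts, the ratio of these genes is 1 for any value above 0, so it tests nothing. In 3 of the lists that camera called both at 10 µM against control and at 20 µM against 10 µM, the 20 µM library lay on the other side of the 10 µM libraries from the shift at 10 µM, histones (median difference -0.88), cholesterol biosynthesis (-1.79) and fatty acid synthesis (-1.47). That difference is between 1 library and 3, and the opposite signs arise in part from the shared 10 µM libraries.

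The 20 µM library differed from the 10 µM libraries in 3903 genes. Depth is argued against, since thinned to the mean depth of the 10 µM libraries it differed in 3920. As to cells of another type, 35 markers of monocytes and granulocytes, lymphocytes, epithelium and fibroblasts that the controls lack had a median of 0.0402 CPM there. Of these markers 3 stood over 1 CPM, with ITGAX highest at 15.4, and LYZ, which the controls express, stood at 18.75. That median pools the cell types, so it argues only against a mixture of most of them. Cells of a single type would raise few of the markers, so whether they were present stays open. Of 21 cholesterol genes changed in the digit-named libraries, 1 (4.76%) lay further in the 20 µM library than in 10 µM replicate 4. That argues against a 10 µM response carried further for these genes in this library. The test was chosen after its result was seen and holds 1 library at 20 µM, so it excludes nothing about the dose. For all genes the share lying further was 70.3% of 3137, between the bounds set, so whether the higher dose extends the response cannot be told apart from other differences of this library.

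The number of changed genes moved from 64 to 3021 when 1 library was left out. With the naming pattern as a covariate it ran from 1195 (without control 4) to 4806 (without the 20 µM library) around 3348, and without the 20 µM library from 1485 (without 10 µM replicate 3) to 2981 (without control 1) around 3021. Neither stayed within 1.5 times nor moved by more than 3 times, the bounds set, so a naming-pattern difference and a wider spread from the 20 µM library may each account for part, and cannot be told apart. With both changes it ran from 3142 to 5177 around 4806, and with the replicate block and a numbered pair left out from 0 (without pair 2) to 4612 (without pair 1). No biological explanation was tested for this.

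Cholesterol genes were higher than control at 10 µM and lower at 20 µM than at 10 µM. The naming pattern is argued against, since within the letter-named libraries the 20 µM library stood a median of -1.65 from 10 µM replicate 4, with 24 of 25 genes lower, while that 10 µM library stood at 1.17 and the 20 µM library at -0.41 from the letter-named controls. Scaling is argued against, since under relative log expression and upper-quartile factors the median was -1.76 or lower. A dose-dependent change is a candidate explanation that stays open, with 1 library at 20 µM. Other differences of that library are open too.

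Culture day stays open for every contrast with control, as 0 control libraries are labelled Day 1, so Lip-1 and the day cannot be told apart.

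For the main comparison, chance is argued against for genes over all splits. That holds only if the libraries can be exchanged freely, with the numbered pairs left aside. Of 35 splits of the 8 libraries, 1, the real one, gave as many genes (1855, with 23 in the highest other split, which follows the naming pattern). For lists, 1 split gave as many (18, with 17 in the highest other split and 14 in the one following the naming pattern). The real split itself gave 17 lists with upper-quartile scaling and 16 with the filter of 1 CPM. That margin is too narrow to exclude chance for lists. Of the 8 splits that part all 4 numbered pairs, the highest other gave 0 genes and 17 lists. As 8 splits are too few for a share under 0.05, chance cannot be excluded with the pairs kept. For 10 µM against control, over all splits and on the same condition, chance is argued against for genes. There 1 of 35 splits gave as many (2842, against 56 in the split that follows the naming pattern). Chance cannot be excluded for lists, where 3 of 35 splits gave as many (17, with 18 in the highest other split). Of the 8 splits that part numbered pairs 2 to 4 in the same way, the highest other gave 3 genes and 18 lists, and these are again too few for a share under 0.05.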

How the results depend on the processing

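Chosen after the data were seen were the list tests at each dose, the alternatives for the named genes at each dose and the counts that leave out a library with a further term or a numbered pair. Of the 92 named genes past the threshold in the main comparison, 0 reversed and 67 kept their call in each fit with all 8 libraries, while the fit of the letter-named libraries lost all 92. Leaving out controls 1 to 4 lost 51, 71, 78 and 68 of them, and leaving out 10 µM replicates 3 and 4 lost 30 and 59. At 10 µM against control 69 of 105 kept it in every alternative run, and at 20 µM against 10 µM 53 of 79, with 0 reversed in both. In the contrasts with control, genes chosen because all treated libraries lie on the same side of every control could hardly reverse when a library is left out. For those genes the lack of reversals is no test of stability. Among genes not past the threshold, 14, 9 and 22 reversed in the main, 10 µM and 20 µM comparisons.

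The number of changed genes in the main comparison (1855) was 3395 with DESeq2, 2815 with the replicate block, 3348 with the naming pattern as a covariate, 0 in the letter-named libraries alone (2694 at an unadjusted p under 0.05, 0 with limma-voom and 1462 with DESeq2) and 3137 in the digit-named ones. Leaving out each library gave 64 (without control 3) to 3021 (without the 20 µM library). Fits within a naming pattern hold 4 libraries, and the cause of the other changes was not tested. At 10 µM the count (2842) was 4657 with the replicate block, 4665 with the naming pattern and 1364 (without 10 µM replicate 3) to 3021 with each library left out. For the difference between naming patterns edgeR called 0 genes (473 unadjusted), 1 without the low-count filter, 12 by DESeq2, 0 by limma-voom and 0 to 2958 with each library left out, the highest without 10 µM replicate 4. The cause was not tested. With an estimated correlation, camera called 0, 0 and 0 lists in the main, 10 µM and 20 µM comparisons, in place of 18, 17 and 17.

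Of the 18 lists called in the main comparison, 16 kept their call and 0 reversed in the other settings with the preset correlation, while pyroptosis kept it in 11 of 15 and heme synthesis in 13 of 15. Pyroptosis (adjusted p = 0.0289) had 0.1196 without the 20 µM library, 0.07305 without control 2, 0.201 with the filter of 1 CPM and 0.0516 with upper-quartile scaling. Heme synthesis (0.02875) had 0.1196 without the 20 µM library and 0.0534 with that filter. In the main comparison the replicate block took OSGIN1, SLCO4C1 and RASGRP3 below the threshold. It brought BCL2, MCL1, MCM3, FECH, GP6, ITGAX, KRT8, IER3, C3 and ZNF296 past it, and changed no list's call. At 10 µM it took 0 of 105 named genes below, and brought GSDMD, BCL2, MCL1, MYC, SOCS2, ABCB10, GP6, ITGAX, KRT8, IER3, RSAD2, C3, HSPA1A, HSPA1B, KLF4, CT45A9, LIN28A and CD36 past it. At 20 µM against 10 µM it took 16 of 79 below and 16 to a value smaller by more than 1.5 times. It brought 8 past it there: BBC3 (1.8, adjusted p = 0.00416), HBG1 (-0.73, 0.01025), HBG2 (-0.68, 0.0210), POLD1 (-0.76, 0.0407), MCM5 (-0.82, 0.0358), SIGLEC6 (-2.415, 0.0117), KRT19 (-1.06, 0.0203) and GP6, which stood at 0.69 without the block and -1.95 with it (adjusted p = 0.646 and 0.0209).

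In the main comparison these log2 fold changes reversed, none of them past the threshold with all libraries. In the digit-named libraries they were CCND1 -0.04408, GSDME -0.9273, GPX4 -0.1244, FTH1 -0.09939, MYC -0.4696, SOCS3 -0.01301, HSPA1A -0.6857, HSPA1B -0.6977 and TRDN 0.1687, and there MYC, HSPA1A and HSPA1B passed (adjusted p = 0.02025, 0.0182 and 0.0145). In the letter-named libraries they were CD68 -0.1223, SMN2 0.9362 and CYP26A1 -0.8659. With the replicate block they were MYC -0.0007267, HSPA1A -0.2555, HSPA1B -0.268 and CYP26A1 -0.3848, with limma-voom HSPA1A -0.2162, HSPA1B -0.2326 and CYP26A1 -0.9075, and with the naming pattern HSPA1A -0.00597 and CYP26A1 -0.02034. Leaving out each library gave GPX4 -0.08124 to 0.193, FTH1 -0.1021 to 0.7183, MYC -0.3984 to 0.3964, SOCS3 -0.1551 to 0.7636, CD14 -0.4551 to 1.789 and SMN2 -2.033 to 0.2753. It gave HSPA1A -2.04 to 1.894, HSPA1B -1.873 to 1.699, SLX1A -0.5126 to 0.3006 and CYP26A1 -0.6227 to 0.5322. The cause was not tested.

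At 10 µM against control, GSDME was -1.088 with limma-voom and SLX1A -0.1074 with the replicate block. Leaving out each library gave GSDME -1.001 to 1.264, FTH1 -0.3613 to 0.03142, HMOX1 -1.279 to 6.147, RSAD2 -0.241 to 1.654 and KLF4 -0.7716 to 0.9198. It gave SLX1A -0.1062 to 0.5529, LIN28A -1.059 to 0.04325, TRDN -0.7276 to 0.3109 and CYP26A1 -0.09631 to 0.8284. The cause was not tested.

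At 20 µM against 10 µM, with the replicate block, the globins were HBZ -0.9289, HBA1 -0.5522 and HBA2 -0.6605, and other genes GSDMD -2.945, HMOX1 -5.788, BMF -0.3224, CFLAR 0.2011, APAF1 0.1998, NEK7 -0.1472, NPC2 -0.1977 and EGR3 -0.6898. That fit also gave IL1A -3.198, SOCS2 -0.1324, ABCB10 0.01546, GP6 -1.948, ITGAX -0.3284, CD3E -0.9407, CD79A -0.3754 and KRT8 -0.1375. In it the 20 µM library is paired with control 1 alone, so these values rest on that control. With the naming pattern as a covariate the values were HBZ -0.5056, HBA1 -0.5492 (adjusted p = 0.0348, past the threshold), HBA2 -0.5427, GSDMD -1.342, HMOX1 -1.376, CFLAR 0.02341 and NEK7 -0.1622. Also in that fit were EGR3 -0.1038, SOCS2 -0.1327, RPL8 0.03582, GP6 -0.2704, CD3E -0.04009 and CD79A -0.6072. The strict filter gave VDAC2 0.009086 and RPL8 0.05647. RPL8 was 0.02595 with relative log expression and with DESeq2, 0.02395 with upper-quartile scaling, 0.00298 without the low-count filter and 0.003468 with limma-voom. Leaving out each library gave HBA1 -0.1479 to 0.5305, HBA2 -0.1281 to 0.564, HMOX1 -0.2695 to 3.139, APAF1 -0.2087 to 0.02169 and NEK7 -0.09599 to 0.108. It gave EGR3 -0.1269 to 0.2237, RPL38 -0.05471 to 0.1821, RPL8 -0.08291 to 0.07125 and CD79A -0.0711 to 1.116. The cause was not tested.

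With 4 libraries per group, the procedure recovered 34% of genes changed 2-fold in simulated counts for the main comparison. Smaller changes may thus be missed here, though the share in these data can differ from the simulated one. Some smaller changes passed, such as RPL8 (-0.39) and VDAC2 (-0.45). For genes near 0 counts in the controls, such as HMOX1, IL1A and AIM2, depth limits the fold change.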

Other observations

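The genes in this part lie outside the naming rule and were chosen after their values were seen. In the 20 µM library, DDIT3 (CHOP), an effector of endoplasmic reticulum stress, stood at 359.9 CPM, against 41.9 to 93.5 in the 10 µM libraries and 9.23 to 24.25 in the controls. HSPA5 (BiP), the main chaperone of that compartment, stood at 3247 CPM, against 589.1 to 821.2 at 10 µM and 488.6 to 669.5 in the controls, and NQO1, an NRF2 target, at 303.2, against 122.5 to 152.3 and 108 to 114.3. Of the sterol genes, HMGCS1 stood at 92.1 CPM in the 20 µM library, 778.7 to 1220 at 10 µM and 138.5 to 170.2 in the controls. INSIG1, a sterol-regulated gene, stood at 98.6 CPM at 20 µM, 651 to 686.6 at 10 µM and 89.8 to 129.1 in the controls.

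LYZ (lysozyme) followed the library names in the controls, at 121.7 and 123.7 CPM in letter-named controls 1 and 4 and 18.3 and 17.5 in digit-named controls 2 and 3. It stood at 106.5 CPM in letter-named 10 µM replicate 4, 19.3 and 26.2 in digit-named replicates 2 and 3, and 18.75 in the letter-named 20 µM library.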
